A study of Mus musculus with 6 samples.

How the data were processed

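RNA of mouse fully-grown oocytes was measured on 6 arrays, 3 from wild-type females and 3 from females carrying a chemically induced Marf1 mutation on both copies, in a mixed C57BL/6J and C3HeB/FeJ background. Per the labels' protocols, females were primed with 5 IU of equine chorionic gonadotropin (eCG) at 21 days of age for 46 hours. The complexes of oocyte and cumulus cells were then released from large antral follicles. Cumulus cells were stripped off with a narrow glass pipette, and RNA from the bare oocytes was amplified by a whole-transcript method, biotin-labelled and hybridised, 1 sample to an array. Groups and replicate numbers were taken from the sample titles.

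The deposited values are log2 expression per probe set, rounded to 2 decimals, 1 column per array. The authors' processing, per the submitters' processing notes, involved GCOS, Affymetrix Expression Console 1.1 and RMA. RMA corrects background, forces the arrays to a common distribution and summarises the probes of each set on the log2 scale. A change in the total RNA of an oocyte is therefore not visible, and every difference is relative to the other probe sets of the same array. The genome build behind the array design is not given in the sources used here, so no coordinates are printed. All 35556 rows of the table were used as deposited.

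Gene names came from the platform annotation. Of the rows, 21789 named 1 gene, 1621 named several and 12146 were not named here, 6617 of these with an ID below the lowest named ID. No gene was named from a row with several. By Entrez ID 21698 of the 1-gene rows matched the RefSeq annotation of GRCm38.p6 and 91 did not, and no symbol needed updating. The annotation served only for names and for which genes neighbour each other. For a gene with several rows (999 of 19938 genes) the row with the highest mean over the 6 arrays was used, and 1 gene had another row past the threshold in the opposite direction. Some 701 rows were identical on all 6 arrays to another row, in 225 groups.

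The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term), two-sided, on the deposited log2 values. The Benjamini-Hochberg adjustment ran over all 35556 rows, with an adjusted p under 0.05 as the threshold. A further count required a change of at least 2-fold. The prior degrees of freedom of the fit were 3.65. The fit, 27 gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

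Each list of at least 5 measured genes was tested against all other genes with camera (correlation between genes preset at 0.01, adjusted over 26 lists) and with camera using a correlation estimated per list. Separately, fry asked whether a list's genes moved one way on balance, with no comparison with other genes. Its mixed form asked whether they moved in either direction, also with no such comparison. For each list the number of genes past the threshold was also counted with the adjustment over the list alone, and Fisher's exact test compared its share of changed genes with that of the other genes. The lists covered the target itself, PP2A subunits, M-phase entry, spindle, meiotic prophase, retrotransposon silencing, DNA damage and p53, oocyte identity, mRNA decay, translation control, interferon, immediate early and heat shock genes, apoptosis, cholesterol synthesis and glycolysis. They also covered germline chromatin regulators, 2-cell-stage genes, ubiquitin ligases, ribosomal proteins, oxidative phosphorylation, the proteasome, histones, olfactory and vomeronasal receptors, small non-coding RNAs, and markers of cumulus and granulosa cells, of theca and stroma, and of blood, immune and endothelial cells. Listed names were matched to current symbols, and to older synonyms where the name was no current symbol. The 95th percentile of the mean level of receptor genes, 4.52 on the log2 scale, served as a description of a dim signal. It is called the receptor-gene level. Of 100 named genes, 29 had the mean of the lower genotype below it. Their differences may be lower bounds and have no settled order, since the deposited values hold no measure of background. Olfr585 lay below the level in both genotypes, so its rise is not read as a lower bound.

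Named genes were Marf1 and Ppp2cb, the 12 largest rises and 12 largest falls among 1-gene rows with an ordinary symbol, past the threshold, with all 3 mutant values on one side of all 3 wild-type values, and up to 4 members per list past the threshold with the largest change. Where another gene is named it was chosen after its values were seen. Fisher's exact test compared the share of changed genes among 100 genes on each side of Marf1 with that elsewhere.

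The pipeline was tested on simulated arrays of 35556 rows for the same comparison. With 50 rows changed at each fold, it recovered 2% of rows changed 1.5-fold, 42% changed 2-fold, 66% changed 4-fold and 94% changed 8-fold. There were 5 false calls, and every sign was right. Far fewer rows were changed than the 2765 called in the data, so these rates do not give the power of the real comparison. On a separate set of simulated arrays camera recovered the 1 shifted list with 0 false lists. Rows there were drawn independently, so this says little about lists of correlated genes. The small number of arrays limits the precision.

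Alternatives were median centring, quantile normalization and cyclic loess of the deposited values, 2 filters on dim rows, tests over 1-gene rows or 1 row per gene, eBayes with an intensity trend with or without robust fitting, array weights, a plain t-test, the replicate number as a block, each array left out in turn, a 1.5-fold limit, and other windows around Marf1. After the data were seen, 5 more kinds were added: the list counts without mutant replicate 3, the test without the unnamed rows of low ID, identical rows counted once, 2 level filters on gene families and on neighbouring risers, and another level filter on small nucleolar RNAs. The growing oocytes that the protocol also mentions were not analysed here.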

Results

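Expression was measured in fully-grown oocytes, the transcriptionally silent germinal-vesicle stage, of 23-day-old mice. There were 3 wild-type and 3 Marf1-mutant samples, each on 1 array with 35556 probe sets. Median log2 expression per array was 4.60, 4.67 and 4.62 in wild type replicates 1 to 3 and 4.56, 4.57 and 4.76 in mutant replicates 1 to 3. Across probe sets the wild-type arrays correlated with each other at r = 0.984 to 0.985 and mutant replicates 1 and 2 at 0.985. Mutant replicate 3 stood apart, at 0.970 to 0.973 with the other mutants, and its values had the smallest spread over probe sets (SD 2.04, against 2.14 to 2.20 on the other arrays). Between genotypes r was 0.95 to 0.961. The first principal component held 52.0% of the variance and separated the genotypes, and the second held 21.7%, with mutant replicate 3 at its far end. The labels call the samples individual, with no statement that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

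The comparison asks which transcripts differ in oocytes without normal Marf1, a gene that oocytes need to resume meiosis. Marf1 itself (probe set 10437852) was lower in the mutant, at 6.18 ± 0.21 against 9.23 ± 0.08 (log2, mean ± SD, n = 3 each). That is a log2 fold change of -3.05 (SE 0.15, 8.26-fold lower, limma adjusted p = 1.0e-04). The mutation is a chemically induced one, and the position of the probes relative to it is not given in the sources used here, so the level checks the labels only in part. Ppp2cb (probe set 10571266), the catalytic beta subunit of protein phosphatase 2A, moved the other way, from 4.88 ± 0.32 to 9.34 ± 0.08, a log2 fold change of 4.46 (SE 0.18, 22.0-fold higher, adjusted p = 5.63e-05). Large changes were mostly rises. Of 19938 genes, 1276 were higher and 806 lower in the mutant, together 10.4%. At a change of at least 2-fold 922 were higher and 221 lower (80.7% higher), at 4-fold 287 and 12, and at 8-fold 80 and 3.

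Over all probe sets, 2765 passed the threshold (7.78%), 1700 higher and 1065 lower, and 1565 of them changed at least 2-fold, 1219 higher and 346 lower. The 1621 rows naming several genes did not lean upward, with 30 higher and 30 lower at 2-fold and 0 and 5 at 8-fold. At an unadjusted p under 0.05 there were 7094. In 30.7% of genes all 3 mutant values lay on one side of all 3 wild-type values, where chance gives 10%. They lay above in 2576 genes and below in 3537. The share of higher calls was 61.5% as deposited and moved with the setting. Cyclic loess normalization gave 2020 higher and 717 lower probe sets (73.8% higher), median centring, which changed no fold change, 67.6% higher, and quantile normalization 1778 higher and 1384 lower (56.2%). It was 53.9% among rows above the median level and 53% with 1 row per gene. Leaving out 1 array gave 1399, 1664 and 1368 changed probe sets without wild-type replicates 1, 2 and 3, 1693 and 1726 without mutant replicates 1 and 2, and 2804 without mutant replicate 3.

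**Figure D1:**
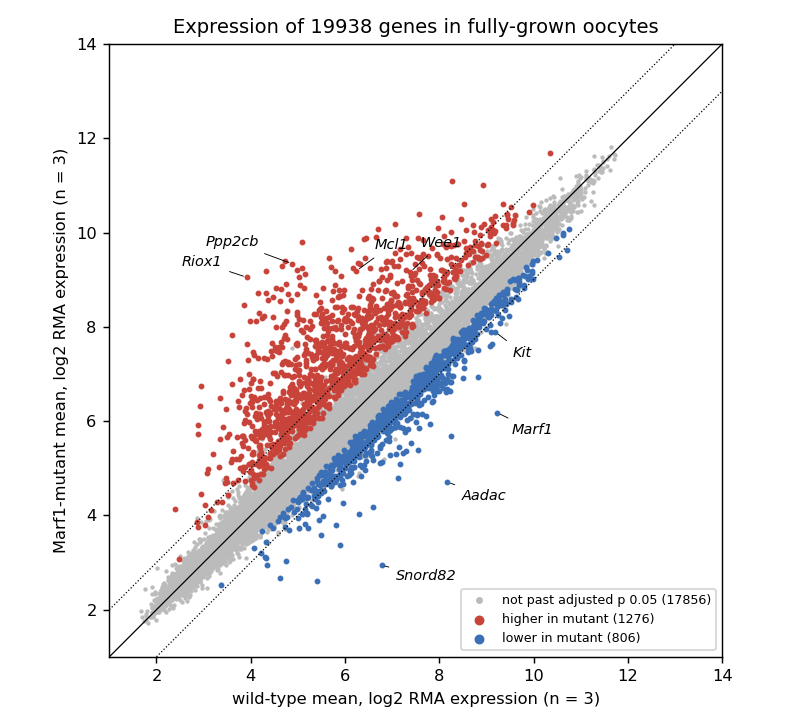
Mean log2 RMA expression of 19938 genes in wild-type (x axis) and Marf1-mutant (y axis) oocytes, n = 3 arrays each. Red and blue points are the 1276 higher and 806 lower genes at adjusted p under 0.05, grey points the others, the solid line equality and the dotted lines a 2-fold change. Red points reach much farther from the line than blue ones, as 287 genes rose and 12 fell at least 4-fold.

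The largest measured rise among the named genes was that of Riox1, a ribosomal oxygenase, from 3.92 ± 0.15 to 9.05 ± 0.14 (log2 fold change 5.13, SE 0.15, adjusted p = 4.16e-05). Next came Osgin2 (4.85), the RNA kinase Clp1 (4.67), Ndufaf1, an assembly factor of respiratory complex I (4.64), Lemd3, a protein of the inner nuclear membrane (4.62), and Kbtbd2 (4.56). Uhrf2, a ubiquitin ligase that binds modified DNA, rose by 4.40, the chromatin factor Jade3 by 4.29, the nuclear import receptor Kpna4 by 4.23, the RNA polymerase III subunit Polr3e by 4.22 and Simc1 by 4.21. The wild-type means of these genes lay between 3.59 for Kpna4 and 4.99 for Polr3e. Those of Riox1, Osgin2, Lemd3, Kbtbd2, Uhrf2, Kpna4 and Simc1 lay below the receptor-gene level of 4.52, so these rises are lower bounds and have no settled order. Each of the rises named here passed the threshold in every fit that left out 1 array.

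Small nucleolar RNAs were frequent among the largest falls. Snord82 had the largest measured fall among the named genes, from 6.77 ± 0.32 to 2.94 ± 0.53 (log2 fold change -3.83, SE 0.29, adjusted p = 3.17e-04). Snord118, the U8 RNA of ribosomal RNA processing, changed by -2.80, Snora75 by -2.01 and Snord47 by -1.93. Aadac, a deacetylase of lipid and drug metabolism, changed by -3.46. Further falls were those of Efcab3 (-2.56), the receptor gene Olfr877 (-2.53), Nlrc4, a sensor of the inflammasome (-2.42), Mdga2 (-2.32), the mitochondrial myosin Myo19 (-2.17) and Ceacam2 (-2.08). The mutant means of the 4 small nucleolar RNAs (2.94, 2.61, 3.79 and 2.68), of Olfr877 (3.36) and of Nlrc4 (4.17) lay below the receptor-gene level. These falls may be lower bounds and have no settled order. Of the 354 small non-coding RNAs measured, 9 fell and 0 rose over all rows, and 6 fell and 0 rose adjusted over the list alone. At unadjusted p under 0.05 in limma 8 were higher and 18 lower. With mutant replicate 3 left out, the list had 1 higher and 8 lower.

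**Figure D2:**
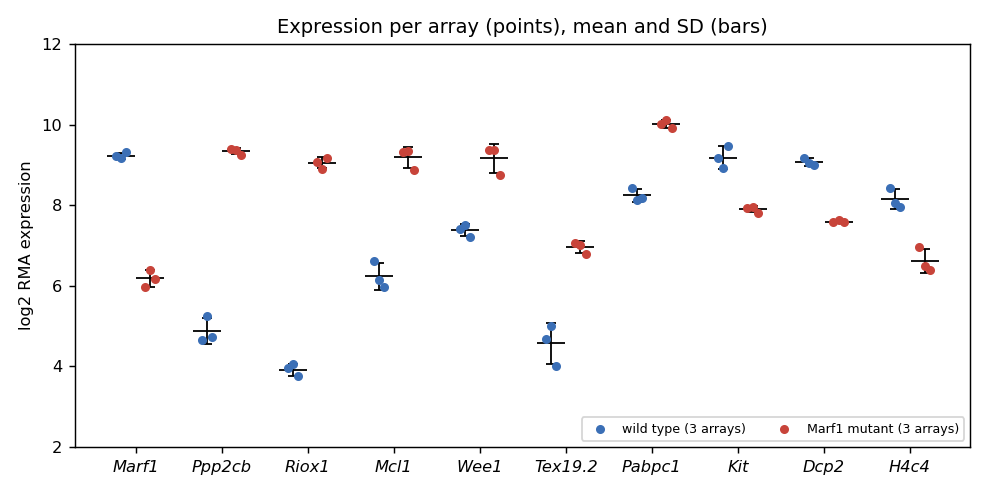
Log2 RMA expression of 10 genes on each array, with points for the 3 wild-type (blue) and 3 Marf1-mutant (red) arrays and black bars for the mean and SD. Ppp2cb lay at 4.65 to 5.25 in wild type and 9.25 to 9.39 in the mutant, and Marf1 at 9.16 to 9.31 and 5.98 to 6.40.

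Of 20 measured subunits and regulators of protein phosphatase 2A, a phosphatase that opposes M-phase kinases, 5 rose and 1 fell (7 and 4 adjusted over the list alone). Besides Ppp2cb, the regulatory subunit Ppp2r5e rose by 1.45, the scaffold Ppp2r1b by 0.93, Ppp2r3a by 0.91 and the activator Ptpa by 0.78, while the scaffold Ppp2r1a changed by -0.68. The other catalytic subunit, Ppp2ca, had a log2 fold change of 0.58 (adjusted p = 0.0725). Among 33 genes of M-phase entry and meiotic arrest 1 rose and 1 fell (1 and 0 adjusted over the list alone). Wee1, the kinase that inhibits Cdk1, rose from 7.38 ± 0.15 to 9.16 ± 0.36 (1.78, SE 0.20, adjusted p = 0.00202), and the phosphatase Cdc14b changed by -1.02. Cdk1 itself had a log2 fold change of -0.14 (SE 0.18, adjusted p = 0.765). Of 42 spindle and chromosome segregation genes 3 fell and 0 rose (3 and 2 adjusted over the list alone, and 10 lower and 4 higher at unadjusted p under 0.05 in limma). These were the kinetochore gene Cenpf (-0.87), Anapc5 of the anaphase-promoting complex (-0.78) and Cdca8 of the chromosomal passenger complex (-0.53). At unadjusted p under 0.05 the PP2A list had 7 higher and 6 lower and the M-phase list 1 and 8. Without mutant replicate 3 the PP2A list had 7 higher and 0 lower, the M-phase list 1 and 0, and the spindle list 3 higher and 1 lower. Ppp2r3a, Cdc14b, Cenpf, Anapc5 and Cdca8 lost the call without at least 1 array, and Ppp2r3a in wild type and Cdc14b in the mutant lay below the receptor-gene level.

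Genes of meiotic prophase and recombination changed more often than other genes, in both directions. Of 32 measured, 4 rose and 6 fell (4 and 7 adjusted over the list alone), a share of 31.3% against 10.4% of other genes (Fisher's exact test, two-sided, p = 0.00112, adjusted p = 0.00973). The other genes include many dim ones, such as 1196 receptor genes, of which 0.502% changed. Genes of matched level were not compared, so the excess is not separated from level. The cohesin subunit Rad21l rose by 2.38, the mismatch repair gene Mlh3 by 2.31, the chromosome axis gene Hormad1 by 1.67 and Trip13, which removes Hormad1 from axes, by 1.06. The cohesin subunit Smc1b changed by -1.08, the synaptonemal complex gene Sycp2 by -0.94 and Brca1 by -0.75. In the retrotransposon silencing list of 39 genes, 3 rose and 2 fell (6 and 5 adjusted over the list alone). Tex19.2 rose by 2.39 and the Piwi gene Piwil2 by 1.89, Tdrd9 changed by -0.93 and Kif17 by -0.80. Of 39 genes of the DNA damage and p53 response 3 rose and 1 fell, over all rows and adjusted over the list alone. Sesn1 rose by 1.42, the damage sensor Xpc by 1.1 and Ei24 by 1.09, and Perp changed by -0.67. At unadjusted p under 0.05 in limma the balance leaned lower, with 5 higher and 10 lower for meiotic prophase, 6 and 11 for retrotransposon silencing and 4 and 7 for the p53 response. With mutant replicate 3 left out, the counts were 5 higher and 4 lower for meiotic prophase, 2 and 2 for retrotransposon silencing and 2 and 0 for the p53 response. Smc1b, Tdrd9, Kif17, Xpc, Ei24 and Perp lost the call without at least 1 array, and Rad21l, Mlh3 and Sesn1 in wild type and Perp in the mutant lay below the receptor-gene level.

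Most of the oocyte growth and identity genes did not pass. Of 42, 3 rose and 2 fell (3 and 3 adjusted over the list alone). Kit, the receptor through which granulosa cells stimulate oocyte growth, changed from 9.18 ± 0.28 to 7.90 ± 0.08 (-1.28, SE 0.17, adjusted p = 0.00419), and Nlrp2, a maternal effect gene, by -0.86. Taf4b rose by 1.13 and the transcription factor Sohlh1 by 0.95. The secreted factors Gdf9 and Bmp15 had log2 fold changes of -0.09 (SE 0.13) and -0.07 (SE 0.16), and the zona pellucida gene Zp3 -0.21 (SE 0.17), none past the threshold. Of 53 genes of mRNA decay and P-bodies 5 rose and 5 fell (7 and 5 adjusted over the list alone). Lsm1 rose by 1.80, Zfp36l2, which destabilises mRNAs with AU-rich elements, by 1.54, and the helicase Ddx6 by 1.38, while Dcp2, the decapping enzyme, changed by -1.49 (SE 0.13, adjusted p = 6.09e-04). Among 30 genes of cytoplasmic polyadenylation and translation control, 2 rose and 2 fell (3 and 7 adjusted over the list alone). Pabpc1, a poly(A) binding protein, rose by 1.77 and Eif3a by 0.96, and the kinase Eif2ak4 changed by -1.14 and Pabpc1l, the oocyte form of the poly(A) binding protein, by -0.59. More genes of each list were lower than higher at unadjusted p under 0.05 in limma, 10 against 4 for oocyte identity, 14 against 7 for mRNA decay and 7 against 3 for translation control. Without mutant replicate 3 these 3 lists had 3, 6 and 2 higher and 2, 3 and 1 lower. Nlrp2, Eif3a and Pabpc1l lost the call without at least 1 array.

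All members of the apoptosis and of the immediate early and heat shock lists that passed were higher. Of 28 apoptosis genes 4 rose and 0 fell (5 and 1 adjusted over the list alone, and 6 and 3 at unadjusted p under 0.05 in limma). They were Birc2 (3.93), Mcl1 (2.95) and Bcl2 (0.76), which oppose cell death, and the protease Casp6 (0.75). Of 29 immediate early and heat shock genes 4 rose and 0 fell (4 and 1 adjusted over the list alone, and 10 and 1 at unadjusted p under 0.05). The chaperones Hspb1, Hsph1 and Hspa1a rose by 1.13, 0.68 and 0.64, and Xbp1, a transcription factor of the unfolded protein response, by 1.05. In the interferon and innate response list of 32 genes Trim25 rose by 3.06 and 0 fell, also adjusted over the list alone, with 2 higher and 3 lower at unadjusted p under 0.05. With mutant replicate 3 left out, these lists had 6, 4 and 1 higher and 0, 0 and 1 lower. Bcl2, Casp6, Hsph1, Hspa1a and Xbp1 lost the call without at least 1 array, and Birc2, Bcl2, Casp6 and Trim25 lay below the receptor-gene level in wild type.

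In metabolism, the lactate and pyruvate carrier Slc16a1 rose by 1.83 and Pgam1 by 1.46, while Pkm changed by -0.70, among 16 glycolysis genes (2 higher and 6 lower adjusted over the list alone). In cholesterol synthesis, Pmvk rose by 1.61, and Sc5d changed by -1.50, Hsd17b7 by -0.78 and Scap by -0.78. Of those 22 genes 2 rose and 3 fell, over all rows and adjusted over the list alone. Of 89 oxidative phosphorylation genes 4 rose and 3 fell, also adjusted over the list alone, with Ndufaf1, Uqcrc1 (1.71) and Atp5g3 (1.11) higher and Cox6a2 (-0.98) lower. At unadjusted p under 0.05 in limma 7 were higher and 22 lower, and the list passed camera as lower without mutant replicate 2 (adjusted p = 0.00752, against 0.156 with all arrays and 0.936 with all arrays and an estimated correlation). Among 61 ribosomal protein genes Rpl9 rose by 3.47 and Rps4l changed by -0.80, also adjusted over the list alone. Rpl9 had 8 rows, and the row used lay at 6.39 in wild type, against a list median of 9.34. Pgam1 had 3 rows, and Pkm and Rps4l 2 each. For each the row with the highest mean was used, a choice that a rise itself helps. Which locus these rows read was not tested. Of 39 proteasome subunits 3 rose and 1 fell (4 and 2 adjusted over the list alone), namely Psmd13 (2.38), Psmd14 (0.90), Psmb5 (0.72) and Psmd1 (-0.62). Of 27 ubiquitin ligase genes of oocytes 2 rose and 1 fell, also adjusted over the list alone, namely Cul4a (1.19), Dcaf1 (0.87) and Fbxw13 (-0.78). Counts at unadjusted p under 0.05 were 2 higher and 6 lower for glycolysis, 3 and 4 for cholesterol synthesis, 4 and 5 for ribosomal proteins, 4 and 6 for the proteasome and 6 and 6 for ubiquitin ligases. Without mutant replicate 3 the ribosomal list had 4 higher and 1 lower, the ubiquitin ligase list 4 and 1 and glycolysis 2 and 3. Cholesterol synthesis then had 3 higher and 2 lower, oxidative phosphorylation 4 and 2 and the proteasome 3 and 1. Pkm, Hsd17b7, Scap, Atp5g3, Cox6a2, Rps4l, Psmd14, Psmb5, Psmd1 and Fbxw13 lost the call without at least 1 array, and Pmvk lay below the receptor-gene level in wild type.

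The histone genes that passed were all lower. Of 27, 3 fell and 0 rose (5 and 0 adjusted over the list alone, and 7 and 0 at unadjusted p under 0.05 in limma), namely H4c4 (-1.53), H2bc1 (-1.37) and H2ac1 (-1.26). Among 37 chromatin regulators of the germline 3 rose and 0 fell (5 and 4 adjusted over the list alone, and 7 and 6 at unadjusted p under 0.05). Tet2, which oxidises methylated DNA, rose by 1.26, the Polycomb gene Ring1 by 0.74 and the histone demethylase Kdm1b by 0.74. Of 15 genes known from the 2-cell embryo 1 rose, AF067061 (2.04), and 1 fell, Arg2 (-0.59). Adjusted over the list alone 6 were higher and 1 lower, at unadjusted p under 0.05 7 and 1, and the median log2 fold change of the list was 0.42. With mutant replicate 3 left out, the histone list had 0 higher and 4 lower, the chromatin list 5 and 0 and the 2-cell list 2 and 1. Ring1, Kdm1b and Arg2 lost the call without at least 1 array.

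**Figure D3:**
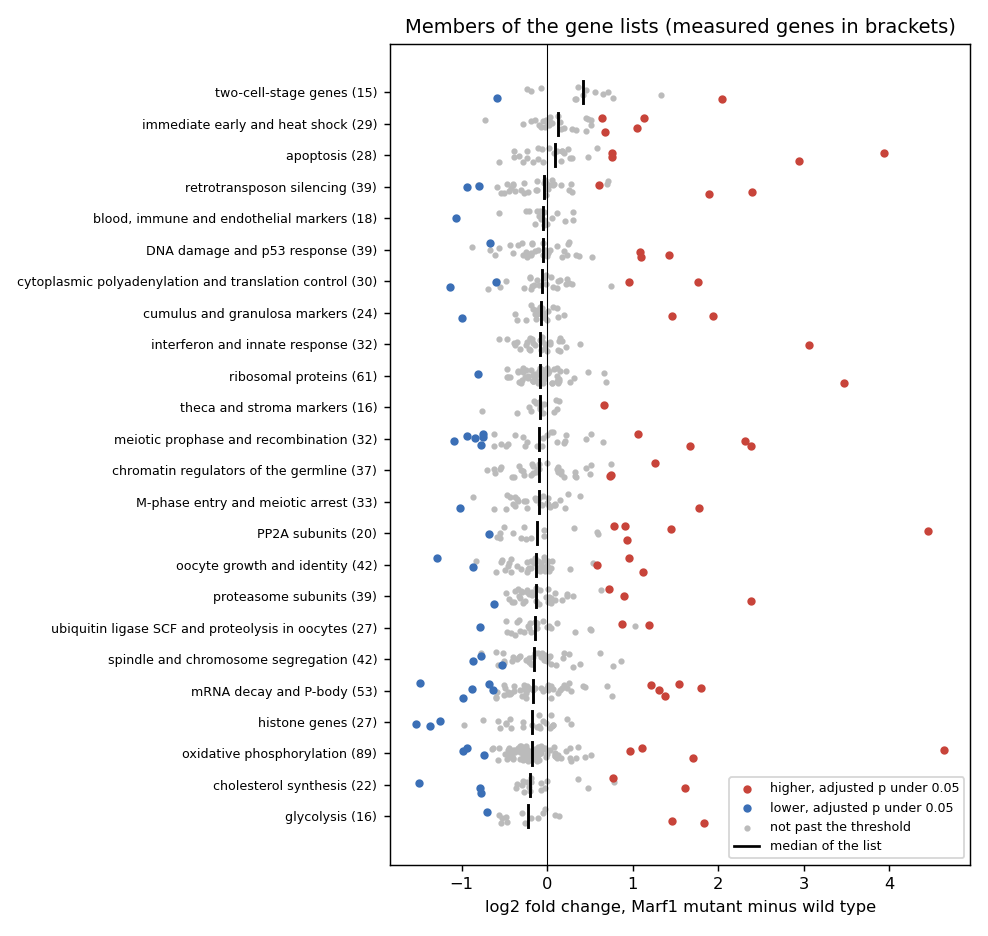
Log2 fold change of each measured member of 24 gene lists (Marf1 mutant minus wild type), with red and blue points for members higher or lower at adjusted p under 0.05, grey points for the others and a black bar for each list's median. List medians lie close to 0, between -0.23 for glycolysis and 0.42 for the 2-cell-stage genes, while single members reach 4.64.

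No list as a whole passed camera after adjustment over 26 lists (0 lists, with 4 at unadjusted p under 0.05). The lowest adjusted p were 0.0648 for the histone genes, lower in the mutant, 0.0648 for the 2-cell-stage genes, higher, and 0.0675 for immediate early and heat shock genes, higher. With an estimated correlation 0 lists passed, with 1 at unadjusted p under 0.05, and each of the 3 had an adjusted p of 0.936. By fry, which asks whether a list's genes moved one way on balance, only the immediate early and heat shock list passed (adjusted p = 0.0123). In fry's mixed form every tested list passed except the receptor genes (mixed adjusted p = 0.350). That form makes no comparison with other genes, so it sets no list apart from them. After quantile or cyclic loess normalization all 3 lists passed camera, at adjusted p of 0.0440 for each and of 0.0262 to 0.0283. Leaving out wild-type replicate 2 gave adjusted p of 0.0134 for histones and 0.0377 for 2-cell-stage genes, and leaving out mutant replicate 1 gave 0.0128 for 2-cell-stage genes and 0.0333 for the receptor genes, as higher. With all arrays the receptor list had a camera adjusted p of 0.275, or 0.936 with an estimated correlation. After cyclic loess its direction was down. Leaving out mutant replicate 2 gave 0.00752 for oxidative phosphorylation and 0.0339 for histones, both as lower. The PP2A, chromatin, meiotic prophase and cumulus lists had a median below 0 and a mean above 0, with camera's direction up in the first 2 and down in the others. For the small non-coding RNAs the median was above 0, the mean below 0 and camera's direction up.

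Among markers of cells that could cling to the oocytes, those of theca and stroma and of blood, immune and endothelial cells were mostly dim. Those of cumulus and granulosa cells were less so. Of 24 cumulus and granulosa markers, 14 lay above the receptor-gene level in wild type, and 2 rose and 1 fell, also adjusted over the list alone. Nr5a2 rose from 8.71 ± 0.18 to 10.17 ± 0.24, while Gja1 (5.59 in wild type) and Esr2 (5.45) had log2 fold changes of 0.06 and 0.12, not past the threshold. Kitl, the ligand of Kit, rose by 1.94 and Ptgs2 changed by -1.0. Of 16 theca and stroma markers Pdgfra rose by 0.67 and 0 fell, also adjusted over the list alone, with 1 higher and 1 lower at unadjusted p under 0.05 in limma. Of 18 blood, immune and endothelial markers Pecam1 changed by -1.07 and 0 rose, also adjusted over the list alone, with 0 higher and 2 lower at unadjusted p under 0.05. The cumulus list had 2 higher and 2 lower at that limit. Above the receptor-gene level in wild type lay 5 of the theca and 6 of the blood markers. Among 1196 olfactory and vomeronasal receptor genes, receptors of sensory neurons, 2 rose and 4 fell (0 and 3 adjusted over the list alone, and 23 and 19 at unadjusted p under 0.05), 0.502% against 11.1% of other genes. They included Olfr666 (2.01), Olfr585 (1.74) and Olfr283 (-1.64). Without mutant replicate 3 the cumulus list had 2 higher and 0 lower, the theca list 0 and 1, the blood list 0 and 1 and the receptors 2 and 4. Ptgs2, Pdgfra, Pecam1 and Olfr585 lost the call without at least 1 array. Kitl, Pdgfra and Olfr666 in wild type and Ptgs2 in the mutant lay below the receptor-gene level. Olfr585 lay below it in both genotypes (2.40 in wild type and 4.14 in the mutant).

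Because the strain background is mixed, genes near Marf1 were compared with the rest. Among 191 measured genes within 100 genes on each side, 22 had changed, against 2057 of 19664 elsewhere. The odds ratio was 1.11 (95% interval 0.679 to 1.75, Fisher's exact test, two-sided, p = 0.634).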

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

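No probe set called with the deposited values had the other sign under any setting. Median centring, the eBayes trend fits, the plain t-test, the replicate block and the tests over fewer rows changed no fold change. In these the sign could not turn. Fits with 1 array left out share most of their arrays with the main fit, so a turned sign was unlikely there too. Marf1 stayed past the threshold, at -2.95 to -3.16 with 1 array left out. Changed probe sets numbered 932 by the plain t-test, with 634 higher, 298 lower and 629 at 2-fold, and 1368 to 2804 with 1 array left out (1071 to 1908 higher, 297 to 896 lower). The highest changed and higher counts, without mutant replicate 3, exceeded those of all 6 arrays (2765 and 1700), and the cause was not tested. Lower probe sets numbered 669 after median centring, and 1646 and 1636 among rows above the median level or the receptor-gene level, where fewer rows are tested. A 1.5-fold limit gave 2707. Lists past the threshold numbered 1 by directional fry, 3 after quantile normalization, 3 after cyclic loess and 1 above the receptor-gene level. They numbered 0 to 2 with 1 array left out, against 0 in the fit as reported, and the cause was not tested. Camera was not run for the plain t-test. With the replicate number as a block, 1946 probe sets changed, 1390 higher and 556 lower, and 2 lists passed. Deviations of arrays of the same number correlated at r = 0.15, -0.10 and 0.03 for numbers 1 to 3. Those of arrays of different number lay between -0.22 and 0.18. Deviations from means of 3 arrays cannot decide whether samples of the same number share more than the number. Of 99 named genes other than Marf1, 59 did not pass by the plain t-test, 21 with the block, 9 to 15 under the 3 normalizations and 11 to 33 with 1 array left out, 36 of them without at least 1 array. Additions made after seeing the data gave 3493 changed probe sets without the unnamed rows of low ID and 2721 with identical rows counted once. Whether dim signal limits the falls was not tested. Snord47, at 4.61 in wild type and so near the receptor-gene level, still fell to 2.68. Risers made up 83.6% of 2-fold changed genes at a mean level over 8 and 71.2% under 5.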

Other observations

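Families of genes sharing a symbol stem, grouped after the data were seen, gave further groups among the 922 genes at least 2-fold higher in the mutant. Of 150 stems with at least 15 genes, Zfp, Rab, Zbtb and Klhl held more such risers than other genes (Fisher's exact test, two-sided). For Rab, the small GTPases of vesicle traffic with some of their binding partners such as Rab11fip2, the count was 12 of 70 genes (17.1% against 4.58%, adjusted p = 0.00298). For Zbtb it was 8 of 42 (adjusted p = 0.0157) and for Klhl, adaptors of Cul3 ubiquitin ligases, 7 of 36 (adjusted p = 0.0244). Among the 12311 genes whose mean over all 6 arrays lay above the receptor-gene level, the adjusted p were 0.0254 for Rab, 0.0813 for Zbtb and 0.0270 for Klhl. A rise helps a gene to pass that filter, as 896 of the 922 risers did, so it does not control for level. Single transcription regulators with large rises, picked after their values were seen, were Tbpl2, the oocyte form of the TATA-binding protein (4.16, SE 0.27), Id3 (3.84, SE 0.27), Id2 (3.07, SE 0.20) and Zbtb5 (3.17, SE 0.18).

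The comparison around Marf1, the other normalizations and the fits with an array left out were planned before the data were examined. The tests on dim risers, neighbouring risers, zinc-finger genes and small nucleolar RNAs were chosen after the data were seen, and those on 4 host genes, on the level filter and on the share of risers without mutant replicate 3 after their values were known. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 2765 changed probe sets, and the highest other gave 0. So few splits cannot give a share under 0.05. Without mutant replicate 3 there were 2804 changed probe sets. The odds ratio of being called near Marf1 was 1.11. Neighbouring pairs of 2-fold risers with different symbol stems numbered 58, against a median of 36 in 10000 random placements (permutation p = 3e-04), and 76 against 64 among genes above the receptor-gene level in at least 3 arrays (p = 0.0621), or 76 against 62 among those whose mean over 6 arrays lay above it (p = 0.0418). Risers passed both filters more often than other genes, partly through their mutant values (912 and 896 of 922, against 12442 and 12278 of all 19856 placed genes), so clustering apart from level stays open.

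Genes at least 2-fold changed were mostly higher in the mutant, 922 against 221. The share of risers among 2-fold probe sets was 75.4% after quantile and 86.3% after cyclic loess normalization. Both were run on values already scaled and assume, as the authors' method does, that most transcripts did not change. They therefore cannot decide whether the authors' scaling is the cause. Mutant replicate 3 as the cause is argued against by a share of 82.3% without it (1371 probe sets higher and 295 lower). More carried-over cumulus cells should raise their markers together. The median log2 fold change was -0.075 (bootstrap 95% interval -0.127 to 0) over 24 markers, 14 of them above the receptor-gene level in wild type. It was -0.06 (-0.17 to 0.06) over the 13 whose mean over 6 arrays lay above that level. These medians argue against more carry-over, although 2 of the 13, Nr5a2 (1.46) and Kitl (1.94), rose. The intervals resample markers, so they measure the spread between markers and not between samples. Loss of Marf1, whose product is known to bind and cut RNA, may let transcripts accumulate that wild-type oocytes keep low, and this stays a hypothesis. Its test did not decide, since 18.3% of risers lay below the receptor-gene level in wild type and 15.4% of fallers did in the mutant (odds ratio 1.23, 95% interval 0.818 to 1.90, Fisher's exact p = 0.328). Dim genes were not frequent among the risers. In wild type 753 of the 922 risers lay above that level, against 12221 of all 19938 genes. By wild-type level, 1.33% of genes under 4 were risers, 8.14% at 5 to 6, 8.72% at 6 to 7 and 0.650% over 9.

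Zinc-finger genes named Zfp were 2-fold risers in 47 of 347 cases (13.5% against 4.47% of other genes, adjusted p = 2.78e-09), with Zfp622 (4.16), Zfp715 (3.73) and Zfp275 (3.06) among the largest, and 6 were 2-fold fallers. The family was not low in wild type, with a median level of 5.24 against 4.97 for other genes. This argues against a low wild-type level as the cause, as does a common odds ratio of 2.79 within 10 bins of that level (95% interval 2.02 to 3.84). The median log2 fold change of all Zfp genes was 0.03, so the family as a whole did not shift. Probe sets that pick up several similar members cannot be told apart from separate changes. Only 2 of 127 neighbouring pairs were both risers, with a median of 2 in random placements, too few to decide. A preference of the mutant genotype's effect for this family may be biological, and no test here separates it from similarity of sequence.

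Small nucleolar and Cajal body RNAs that changed were all lower, 9 of 54 measured, of which Snord82 and Snora75 lie in the same host gene, Ncl. The host genes Ncl, Gas5, Hspa8 and Tcp1 did not fall as their RNAs did. The lowest 95% limit of those 4 hosts' log2 fold changes was -0.44, while the RNAs changed by -1.40 or more. These 4 were grouped after their values were seen, leaving out Srcap, so the values describe them and are no test. Over all 5 measured hosts the median was 0.15, but Srcap, host of Snora30, fell (-0.70, adjusted p = 0.0183). A lower host transcript therefore stays open as a cause for Snora30. For Snord118, Scarna17 and Snord49a no measured gene around them was found. Whether these 3 have a host was not examined, so the question could not be asked of them. Lower recovery of short RNAs in the mutant samples stays open: the median was -0.76 (bootstrap 95% interval -1.54 to -0.33) over 18 RNAs above the receptor-gene level in at least 3 arrays, a filter that the falls themselves help to pass, -0.49 (-1.40 to -0.25) over 16 chosen by their mean over all 6 arrays, and -0.18 over all 54. It cannot be told apart from a lower level of these RNAs in mutant oocytes, which predicts the same medians.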
